A study of Mus musculus with 13 samples.

How the data were processed

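RNA from the submandibular gland, a major salivary gland, was sequenced in 13 libraries from mice of 1 year of age. Per the labels, glands were taken on day 300 after treatment. Irradiated mice had received an adeno-associated virus vector in the gland 10 days before irradiation. That vector carried green fluorescent protein (AAV2-GFP) in 5 libraries, called IR_GFP here, or neurturin (Cere-120, AAV2-NRTN) in 5 libraries, called IR_NTN here. The remaining 3 libraries came from mice that were not irradiated (NonIR), and whether those mice received any vector is not given in the sources used here. In both comparisons with NonIR, irradiation and vector are therefore not separated. Neurturin is a growth factor of the GDNF family that acts on parasympathetic neurons through the receptors Gfra2 and Ret. The labels do not tie replicates to separate animals, so the p-values of single genes and of list means measure the spread between these libraries. The strain is given as CH3.

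Per the labels' protocols, RNA was isolated with a column kit, cDNA was made by a SMART-Seq v4 reaction and libraries were tagged with Nextera XT and read on a NextSeq 500. Per the submitters' processing notes, reads were aligned with STAR 2.5.2a to GRCm38.p3, which the notes also call mm10, and DESeq2, edgeR and limma were used. The counting tool and the part each package played are not given in the sources used here. The series description gives another instrument, other aligners and triplicates, which does not match the 13 labelled libraries. The sample labels were followed.

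The authors deposited a table of raw read count values per gene for all 13 libraries, with 48733 entries, of which 48709 are genes and 24 are spike-in and transgene sequences. The authors also deposited a table of normalised signal values, which on testing were each library's counts times 1 constant per library, in CPM (reads scaled to a common library size) of the TMM effective library. That table holds the 17957 entries with at least 6 reads in at least 1 library. The count table was used for every result except 1 alternative, which used the deposited normalised signal. Libraries held between 9724304 reads (IR_GFP 1) and 16771004 reads (IR_GFP 4). Counts of 0 allow up to 3 reads, and intervals and floors cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Gene symbols came from the deposited table and otherwise from GENCODE mouse release 21, which also gave coordinates on GRCm38 and gene types. Of the genes tested, 36 had no symbol.

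Genes were kept by filterByExpr with the group, which left 14727. Library sizes were scaled by TMM, and the quasi-likelihood F test of edgeR 4.0.16 (robust, legacy off, R 4.3.3) was fitted to all 13 libraries with 1 mean per group. The common dispersion was 0.0700, a biological coefficient of variation of 0.265, with 10 residual degrees of freedom and a median prior of 5.64. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each adjusted p of a gene printed below comes from this test unless another tool is named. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values printed below are scaled by TMM. The 3 comparisons were IR_GFP with NonIR, IR_NTN with IR_GFP, and IR_NTN with NonIR.

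Before the data were examined, 30 lists of marker and pathway genes were fixed, together with the tests, most of the alternatives below and the rule for naming genes. The lists covered secretory, ductal, basal and myoepithelial cells, nerve and glia, immune and stromal cell types, neighbouring tissues and stress or growth programmes. A list was tested with at least 3 members, and 29 were tested; the sex check list was used only to compare libraries. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the 29 lists of a comparison. Camera compares the genes of a list with the other genes tested, and the preset correlation is assumed, not estimated from these libraries. Other splits of the libraries, given at the end, called about as many lists at this preset, so its adjusted p-values overstate how firm a list is. Beside it stand camera with an estimated correlation and fry. For fry, the directional p asks whether a list's genes move on balance 1 way and the mixed p whether they change in either direction. Neither compares the list with other genes. An exact permutation test of each list's mean per library was added after the data were seen. It is two-sided, its smallest possible p is 0.0179 for 3 against 5 libraries and 0.00794 for 5 against 5. A lone list at that p adjusts over 29 lists to 0.518 or 0.230, so this test has little room to call any. List means were log2 CPM with a prior count of 2, centred per gene. For single members the text also gives p-values adjusted over the list alone.

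Named genes were chosen by rule: among genes past the threshold with mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted model, up to 12 of the highest and 12 of the lowest fold changes. With fewer than 6 in a direction, genes with the lowest p fill it and are given as values. Up to 4 members per list were named by lowest p, with Nrtn, Gfra2, Ret, Chat, Vip, Aqp5, Chrm3 and Cdkn1a always, and 10 genes of opposite direction in the comparisons that share the IR_GFP libraries.

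Because comparisons share libraries, their overlap was set beside 40 simulated sets of unchanged groups with the same sharing and beside 20 splits of the IR_GFP libraries into separate controls. The simulated sets drew each gene on its own, whereas real genes move together, so the simulated ranges can be too narrow. The test was also run on simulated data with planted changes. The 2-fold and 4-fold changes were planted only in genes with a mean of at least 20 reads, so genes of lower counts are not covered. More genes were changed than were called in the real comparisons. This eases the adjusted threshold, so the shares found may overstate the power here. Of 300 genes changed by 2-fold over 3 runs, the test found 51.3% in IR_GFP against NonIR, 67.7% in IR_NTN against IR_GFP and 44.7% in IR_NTN against NonIR. At 4-fold it found 92.7%, 94.7% and 92.3%, and 4.00%, 5.42% and 5.30% of the genes it called had not been changed.

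Alternatives tried were DESeq2 size factors, library size alone, TMM without the 20 most abundant genes, no low-count filter, CPM above 1 in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom with and without sample quality weights, the legacy form of the edgeR fit and limma-trend on the deposited signal with a pseudocount of 0.5. Others were fits of only the libraries compared, the replicate number as a block, a threshold of 0.1, a log2 fold threshold of 1 and leaving out each library in turn. Leaving out IR_GFP 1 and 2 together and the acinar secretory list mean as a covariate were added after the data were seen. Raw reads were not used here, so alignment and counting were not repeated. Plots were drawn with matplotlib 3.10.9.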

Results

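In irradiated glands given AAV2-GFP (IR_GFP), transcripts of Ccdc62 and Tef rose and those of Il1rn and Rab27a fell against non-irradiated glands (NonIR). Rab27a, a small GTPase of secretory granule release, fell by 1.01 on the log2 scale (SE 0.16, adjusted p = 0.0452, edgeR quasi-likelihood with Benjamini-Hochberg). It went from 1233 ± 115 CPM (SD, n = 3) to 614 ± 130 CPM (SD, n = 5). Il1rn, the secreted antagonist of the interleukin-1 receptor, fell by 1.54 (SE 0.24, edgeR adjusted p = 0.0452), from 7.50 ± 1.79 to 2.57 ± 0.629 CPM. Tef, a transcription factor whose transcript follows the circadian clock, rose by 1.15 (SE 0.19, edgeR adjusted p = 0.0452), from 19.8 ± 0.799 to 43.7 ± 11.3 CPM. Ccdc62, a coiled-coil protein gene, rose by 1.25 (SE 0.19, edgeR adjusted p = 0.0452), from 4.52 ± 0.780 to 10.8 ± 1.55 CPM. For each of these 4 genes the 5 IR_GFP libraries and the 3 NonIR libraries did not overlap, which the rule for naming requires.

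Rab27a (ENSMUSG00000032202) lies on GRCm38 chromosome 9 from 73044854 to 73097629, Il1rn (ENSMUSG00000026981) on chromosome 2 from 24336853 to 24351494, Tef (ENSMUSG00000022389) on chromosome 15 from 81802421 to 81826863 and Ccdc62 (ENSMUSG00000061882) on chromosome 5 from 123930679 to 123969895, all annotated as protein coding. The unannotated transcript Gm37795, outside the naming rule and named after its values were seen, rose by 1.51 (edgeR adjusted p = 0.0452), from 37.8 ± 5.85 to 108 ± 33.6 CPM. In total 5 genes of 14727 passed, 3 higher and 2 lower, and 1293 had an unadjusted p under 0.05 where 736 would by chance. Groups did not overlap for 757 genes, 5.14% of those tested against 3.57% by chance. The same test called 17 genes without IR_GFP 1, 6 without IR_GFP 4, 1 without NonIR 1 or IR_GFP 2, and 0 without any 1 of NonIR 2, NonIR 3, IR_GFP 3, IR_GFP 5 or IR_NTN 1 to 5. In settings that called 0 genes, between 754 and 1320 had an unadjusted p under 0.05; DESeq2 called 73 genes and limma-voom called 0.

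Genes that did not pass the threshold are given as values. Zdhhc2, a palmitoyltransferase, had a log2 fold change of −0.89 (edgeR adjusted p = 0.0533), with 42.2 CPM in NonIR and 22.7 in IR_GFP. Tbx3, an epithelial transcription factor, stood at −0.79, and the small GTPase Arl4a at −0.63 (edgeR adjusted p = 0.0659 for both). Spata13, an exchange factor for small GTPases, stood at −0.80 (edgeR adjusted p = 0.104). On the higher side were the SUMO protease Senp3 at 0.79 and the carnitine palmitoyltransferase Cpt1c at 1.45 (edgeR adjusted p = 0.0863 for both) and Nol9 at 0.74 (edgeR adjusted p = 0.156).

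Among the lists, the granular convoluted tubule, the growth factor secreting duct segment of this gland, was lower in IR_GFP than in NonIR, with 17 of 19 members lower and a median log2 fold change of −0.65 (camera adjusted p = 5.78e-06; adjusted p = 0.578 with an estimated correlation). Its members Egf (−1.001) and Crisp3 (−0.75) did not pass singly, and the kallikrein Klk1 stood at 0.54; kallikrein genes are near-identical copies, so their single values are uncertain. The list mean was −2.19 in IR_GFP 1 and −1.10 in IR_GFP 5, and the groups' means were −0.43 ± 1.21 (SD) and 0.50 ± 0.27 (SD), with an exact permutation p of 0.232. Macrophage and myeloid genes were higher, 18 of 22 members, at a median of 0.39 (camera adjusted p = 0.00374; adjusted p = 0.442 with an estimated correlation). Their list mean was 0.23 ± 0.088 in IR_GFP and −0.08 ± 0.065 in NonIR (SD), an exact permutation p of 0.0179, which is the smallest possible here; without IR_GFP 1 and 2 together the camera adjusted p was 0.0641. B and plasma cell genes were higher, 17 of 18 members, at a median of 0.80 (camera adjusted p = 0.00374; adjusted p = 0.442 with an estimated correlation; exact permutation p = 0.125). Members by lowest p were Cd79a of the B cell receptor at 1.27, the delta heavy chain Ighd at 1.40 and the B cell attractant Cxcl13 at 1.20 (0.34 without IR_GFP 5), and for macrophages the lectin Mrc1 at 0.74, the receptor Trem2 at 0.78, Adgre1 at 1.01 (0.36 without IR_GFP 5) and lysozyme Lyz2 at 0.67. No member of these lists passed singly over all genes or adjusted over the list alone.

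The unfolded protein response was lower at a median of −0.19, with 13 of 18 members lower (camera adjusted p = 0.00374; adjusted p = 0.442 with an estimated correlation), and without IR_GFP 1 its camera adjusted p was 0.0904. Its fry adjusted p was 0.326 in the directional form and 0.00224 in the mixed form. Adjusted over the list alone, 5 chaperone genes of the endoplasmic reticulum were lower, against 0 over all genes: Hsp90b1 (−0.49, edgeR p adjusted over the list alone = 0.0236), Dnajc3 (−0.47, 0.0236), Pdia4 (−0.35, 0.0348), Calr (−0.38, 0.0487) and Hspa5 (−0.34, 0.0487). Duct genes were lower at a median of −0.15 with 14 of 17 members lower (camera adjusted p = 0.0110; adjusted p = 0.442 with an estimated correlation), and the camera adjusted p was 0.0691 without NonIR 1 and 0.0679 without NonIR 3. Among duct members, the sodium channel subunit Scnn1b stood at −0.58 and the proton pump subunit Atp6v1b1 at −0.42, while the ionocyte factor Ascl3 stood at 0.97.

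Extracellular matrix genes were higher at a median of 0.34, 25 of 28 members (camera adjusted p = 0.0126; adjusted p = 0.698 with an estimated correlation), with camera adjusted p of 0.368 without IR_GFP 1, 0.0626 without IR_GFP 2 and 0.101 without NonIR 1. Genes of the p53 and DNA damage response were higher at a median of 0.26, 17 of 23 members (camera adjusted p = 0.0278; adjusted p = 0.552 with an estimated correlation), with camera adjusted p of 0.145 without IR_GFP 1, 0.118 without IR_GFP 2 and 0.283 without NonIR 1. Its member Gdf15, a stress cytokine, stood at 1.29, the cell death gene Bbc3 at 0.88 and the DNA polymerase Polk at 0.74. Senescence-associated genes were higher at a median of 0.50, 11 of 12 members (camera adjusted p = 0.0337; adjusted p = 0.641 with an estimated correlation), with camera adjusted p of 0.221 without IR_GFP 1, 0.0906 without IR_GFP 2, 0.2145 without NonIR 1 and 0.0501 without NonIR 3. Interferon response genes were higher at a median of 0.35, 26 of 33 members (camera adjusted p = 0.0278; adjusted p = 0.712 with an estimated correlation). That camera adjusted p was 0.132 without IR_GFP 2, 0.724 without IR_GFP 4, 0.101 without NonIR 1 and 0.955, with the direction turned, without NonIR 3. Of 29 lists, 9 passed camera, 3 of them lower; with an estimated correlation 0 passed and 1 had an unadjusted p under 0.05. The directional fry test called 0 (4 unadjusted), and the exact permutation test called 0 after adjustment (1 unadjusted). Camera called 4 lists without NonIR 1, and 5 without IR_GFP 1 or IR_GFP 2.

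In irradiated glands given the neurturin vector (IR_NTN), the matrix gene Dpt and the complement inhibitor gene Serping1 fell against IR_GFP. Serping1, which encodes the C1 inhibitor, fell by 1.21 on the log2 scale (SE 0.16, edgeR adjusted p = 0.0175), from 61.5 ± 16.6 CPM (SD, n = 5) to 26.6 ± 4.35 CPM (SD, n = 5), with 43.65 ± 3.30 CPM in NonIR. Dpt, which encodes the fibroblast protein dermatopontin, fell by 1.33 (SE 0.18, edgeR adjusted p = 0.0175), from 17.2 ± 4.47 to 6.85 ± 1.33 CPM, with 14.5 ± 1.15 CPM in NonIR. The 5 libraries of each group did not overlap for either gene, which the rule for naming requires. The phospholipase gene Pla1a, outside the naming rule and named after its values were seen, fell by 1.94 (edgeR adjusted p = 0.0267), from 2.02 ± 0.491 to 0.523 ± 0.113 CPM. Serping1 (ENSMUSG00000023224) lies on GRCm38 chromosome 2 from 84765387 to 84775444 and Dpt (ENSMUSG00000026574) on chromosome 1 from 164796644 to 164824266, both protein coding.

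In this comparison 3 of 14727 genes passed, all 3 lower, and 896 had an unadjusted p under 0.05, 549 of them lower, where 736 would by chance. Groups did not overlap for 164 genes, 1.11% against 0.794% by chance. The same test called 11 genes without IR_GFP 4, 1 without IR_GFP 5, IR_NTN 2 or IR_NTN 3, and 0 without IR_GFP 1, IR_NTN 1, IR_NTN 4 or IR_NTN 5. In settings that called 0 genes, between 573 and 939 had an unadjusted p under 0.05; DESeq2 called 38 genes, 35 of them lower, and limma-voom called 3. Genes given as values were the central complement component C3 (−1.02, edgeR adjusted p = 0.0602), with 29.0 ± 2.74 CPM in IR_GFP and 14.3 ± 3.89 in IR_NTN, and the complement protease C1s1 (−1.11, edgeR adjusted p = 0.0729). Pdgfra, the growth factor receptor of fibroblasts, stood at −1.04 and the myeloid gene Pld4 at −0.94 (edgeR adjusted p = 0.139 for both). On the higher side, the mitotic gene Cdca8 stood at 1.10 (edgeR adjusted p = 0.179), the protease Adamts15 at 0.71 (0.205), Scrn1 at 1.31 (0.254), Rgl2 at 0.49 (0.381) and Car8 and Tbx3 at 0.82 and 0.48 (0.391 for both, edgeR).

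**Figure D1:**
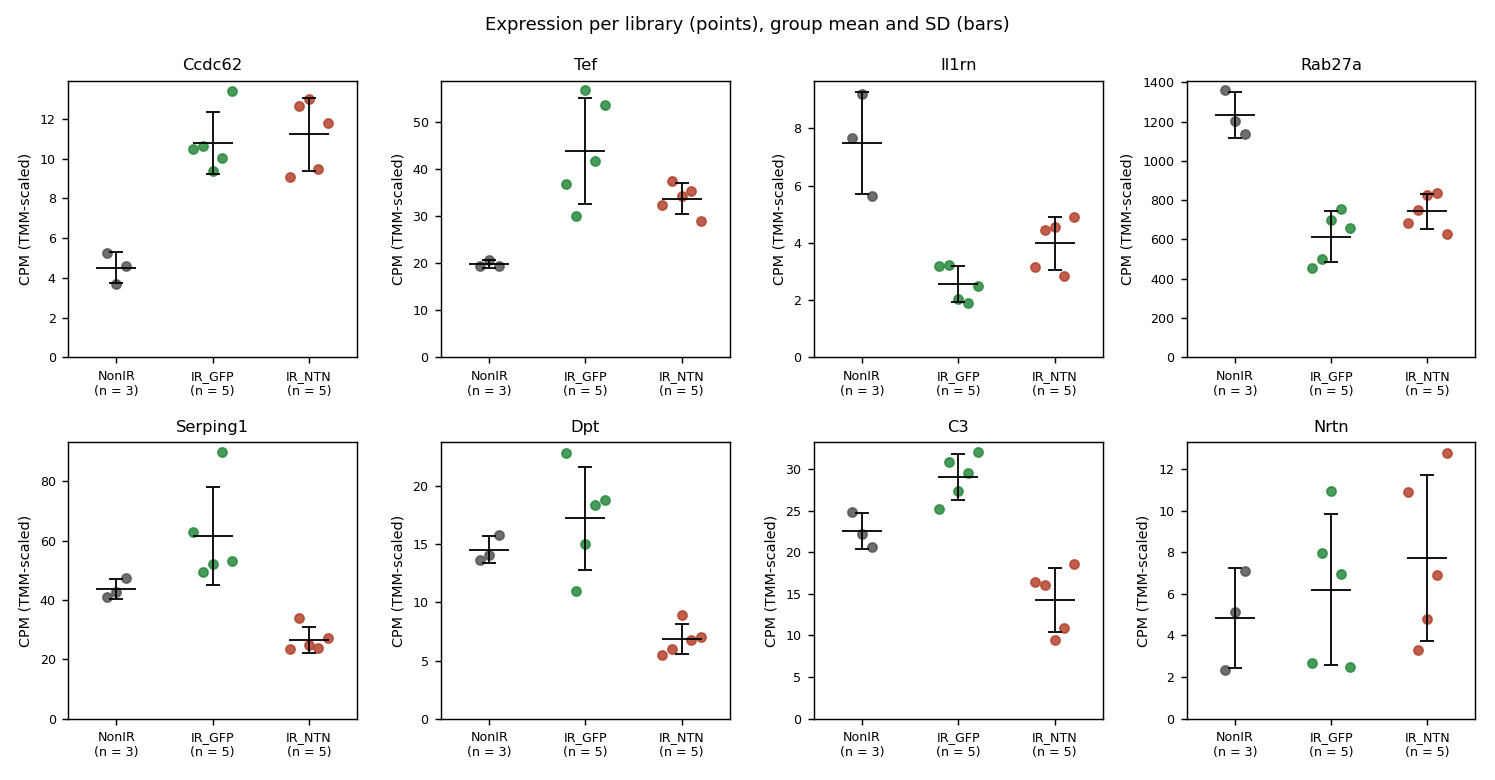
CPM, TMM-scaled, of 8 genes in the 13 libraries by group; points are libraries, horizontal marks are group means and bars are 1 SD. Serping1 and Dpt sit lower in the 5 IR_NTN libraries than in the 5 IR_GFP libraries, and Nrtn overlaps between all 3 groups.

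Macrophage and myeloid genes fell in IR_NTN against IR_GFP, 20 of 22 members lower at a median of −0.40, and this list also passed camera with an estimated correlation (camera adjusted p = 1.21e-09; adjusted p = 0.0181 with an estimated correlation). The list mean was −0.18 ± 0.20 in IR_NTN and 0.23 ± 0.088 in IR_GFP (SD), an exact permutation p of 0.00794, the smallest possible with 5 libraries against 5. Adjusted over the list alone, 7 members were lower, against 0 over all genes. Among these, lysozyme Lyz2 stood at −1.20 (edgeR p adjusted over the list alone = 0.0106), the pore protein Mpeg1 at −0.44 and the surface receptor Adgre1 at −1.38 (both 0.0248), and the Fc receptor Fcgr3 at −0.59 (0.0455). Adgre1 rested in part on IR_GFP 5, without which it stood at −0.73. B and plasma cell genes were lower, 17 of 18 members, at a median of −0.93 (camera adjusted p = 7.26e-09; adjusted p = 0.0815 with an estimated correlation; exact permutation p = 0.0159), with 0 members past the threshold over all genes or adjusted over the list alone and 6 at an unadjusted p under 0.05. Cxcl13 stood at −1.71 (−0.83 without IR_GFP 5), the plasma cell genes Mzb1 at −1.47 and Jchain at −2.38 (−1.79 without IR_GFP 1), and Cd79a at −0.94.

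Granulocyte and mast cell genes were lower, 4 of 4 members, at a median of −1.10 (camera adjusted p = 0.00100; adjusted p = 0.0604 with an estimated correlation; fry adjusted p = 0.0106 directional and 0.3645 mixed). Of the 15 members of this list only 4 passed the filter, and 1 of these, Ltf, stood at −0.52 (0.08 without IR_GFP 2). The mast cell proteases Cma1 at −1.94 and Tpsb2 at −1.68 (−2.28 without IR_NTN 5) passed when adjusted over the list alone (edgeR, 0.000376 and 0.0225), against 0 over all genes. No other member of the list passed. Extracellular matrix genes were lower, 23 of 28 members, at a median of −0.38 (camera adjusted p = 7.86e-07; adjusted p = 0.555 with an estimated correlation; fry adjusted p = 0.430 directional and 0.0415 mixed). Adjusted over the list alone, 5 members were lower and 1 higher, against 0 over all genes: the lower ones included Dcn at −0.69 and Mmp2 at −1.08 (edgeR p adjusted over the list alone = 0.00219 for both), Fbn1 at −1.08 (0.0101) and Lum at −1.09 (0.0104). Without IR_GFP 1 and 2 together, an alternative chosen after seeing the data, the median of the matrix list was −0.04 and its camera adjusted p was 0.0583.

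Cell cycle genes were higher in IR_NTN than in IR_GFP, 20 of 22 members, at a median of 0.65 (camera adjusted p = 1.21e-09; adjusted p = 0.245 with an estimated correlation). The list mean was 0.37 ± 0.23 against −0.25 ± 0.43 (SD), an exact permutation p of 0.0238. The mitotic genes Ube2c (1.43), Plk1 (1.365), Cdc20 (1.08) and Aurka (0.65) had the lowest p, with 0 members past the threshold over all genes or adjusted over the list alone and 8 at an unadjusted p under 0.05. Granular convoluted tubule genes were higher, 17 of 19 members, at a median of 0.27 (camera adjusted p = 0.000178; adjusted p = 0.555 with an estimated correlation), with a camera adjusted p of 0.432 without IR_GFP 1.

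Genes of MHC class II were lower at a median of −0.61, 9 of 10 members (camera adjusted p = 0.000927; adjusted p = 0.555 with an estimated correlation), with H2-Aa at −0.70 and Cd74 at −0.65 and a camera adjusted p of 0.137 without IR_GFP 4. Copies within that gene family are close in sequence, so single members are uncertain. Interferon response genes were lower at a median of −0.35, 29 of 33 members (camera adjusted p = 0.000211; adjusted p = 0.555 with an estimated correlation), with 0.284 without IR_GFP 4. T and NK cell genes were lower at a median of −0.38, 20 of 23 members (camera adjusted p = 0.00194; adjusted p = 0.555 with an estimated correlation), with 0.110 without IR_GFP 4, 0.2315 without IR_GFP 5 and 0.1115 without IR_NTN 3. Parasympathetic and neuronal genes were lower at a median of −0.995, 9 of 10 members (camera adjusted p = 0.0277; adjusted p = 0.555 with an estimated correlation). That camera adjusted p was 0.0608 without IR_GFP 1, 0.142 without IR_GFP 4, 0.127 without IR_NTN 4 and 0.106 without IR_NTN 5. Only 10 of the 27 neuronal list members passed the filter, and the exact permutation p of the list mean was 0.159. The list mean was 1.45 in IR_GFP 1. Without IR_GFP 1 and 2 together the median was −0.27, and Snap25 stood at −1.82 (−0.81 without IR_GFP 1). Of 29 lists, 10 passed camera, 8 lower and 2 higher; 1 passed with an estimated correlation, 2 by directional fry and 0 by exact permutation after adjustment, where 4 had an unadjusted p under 0.05.

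**Figure D2:**
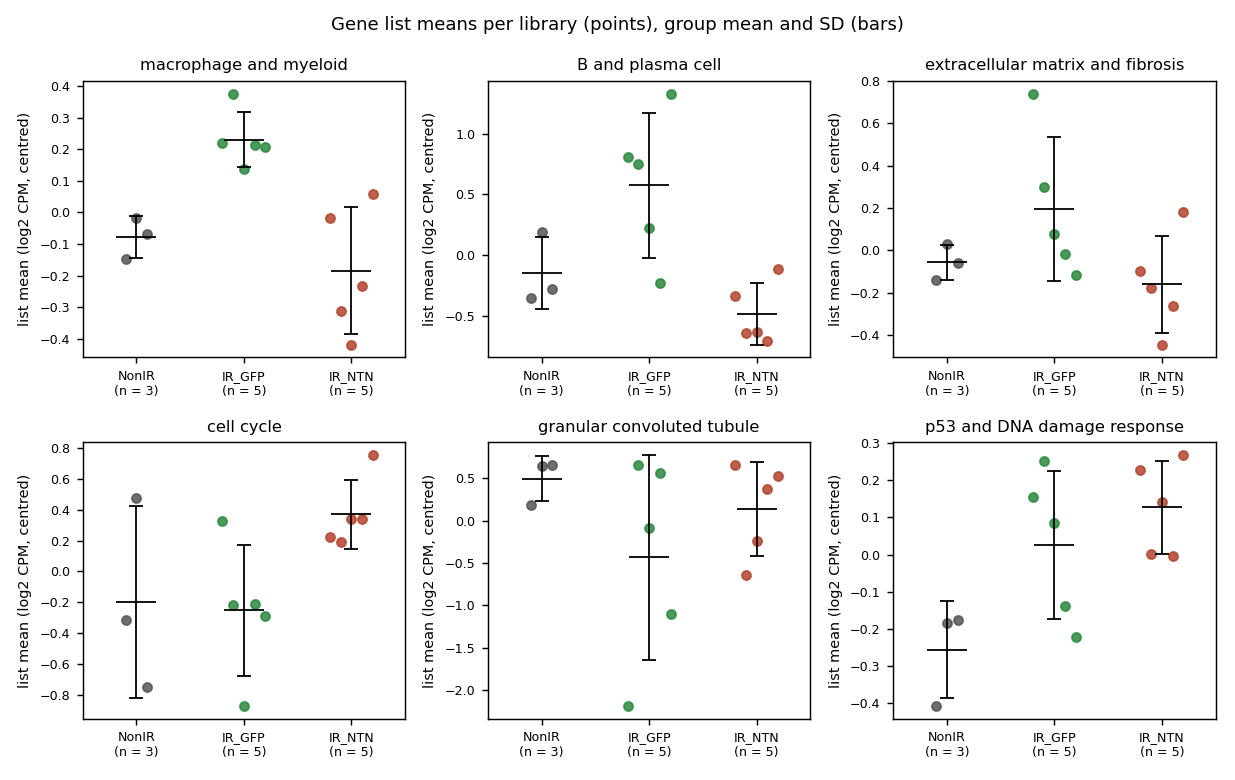
Mean log2 CPM of 6 gene lists, centred per gene, in the 13 libraries by group; points are libraries, horizontal marks are group means and bars are 1 SD. The macrophage list mean is −0.18 in IR_NTN and 0.23 in IR_GFP, and the granular convoluted tubule list mean reaches −2.19 in IR_GFP 1.

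Against non-irradiated glands, IR_NTN glands had higher Ccdc62 and Gm37795. Ccdc62 rose by 1.31 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0227), from 4.52 ± 0.780 CPM (SD, n = 3) to 11.2 ± 1.82 CPM (SD, n = 5). Gm37795 rose by 1.82 (SE 0.24, edgeR adjusted p = 0.0183), to 134 ± 22.4 CPM, and the neuronal membrane gene Slitrk4 fell by 4.06 (SE 0.68, edgeR adjusted p = 0.0227), from 0.866 to 0.0447 CPM. Slitrk4 had 3 reads in all of IR_NTN and 33 in NonIR, a ratio of 0.0505 (exact Poisson 95% interval 0.00991 to 0.161). Its log2 fold change ran from −4.30 to −1.32 over the alternatives, and its call was lost in 14 of 25. Gm37795 and Slitrk4 lie outside the naming rule and were named after their values were seen, and DESeq2 gave Slitrk4 no adjusted p. Ccdc62 and Gm37795 were also the 2 genes called in the same direction in IR_GFP against NonIR, where simulated unchanged groups with the same shared controls gave a mean of 0.05 and at most 1. Each gene was drawn on its own in those groups, so their range can be too narrow. Those groups held no changed genes, so few could pass and a count near 0 was set in advance. The overlap is therefore not evidence of a common change beyond the shared NonIR libraries. Across genes, log2 fold changes of these 2 comparisons correlated at r = 0.638, against 0.639 on average in the simulated groups (0.617 to 0.665). Of 14727 genes 3 passed, and 1174 had an unadjusted p under 0.05 where 736 would by chance. Groups did not overlap for 960 genes, 6.52% against 3.57% by chance. The count was 2 without NonIR 1, 1 without IR_NTN 2 and 0 without NonIR 2, NonIR 3, IR_NTN 3 or IR_NTN 5, and 2 genes of the fit without NonIR 1 included 0 of the 3. In settings that called 0 genes, between 479 and 1245 had an unadjusted p under 0.05; DESeq2 called 31 genes and limma-voom called 1.

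Genes given as values included Ccdc137 (0.79, edgeR adjusted p = 0.0730), the checkpoint gene Topbp1 (0.73, 0.243), Zfp952 (0.67, 0.252), Senp3 (0.80, 0.128) and Cpt1c (1.25, 0.263, all edgeR). On the lower side Dpt stood at −1.09, the cytoskeletal gene Dpysl3 at −0.71, Zdhhc2 at −0.79 and Mrfap1 at −0.69 (edgeR adjusted p = 0.128 for each), and Pdgfra at −1.07 (edgeR adjusted p = 0.238). Cst10, a cystatin, stood at −7.81 (SE 1.47, edgeR adjusted p = 0.128), with 0.205, 3.80 and 21.6 CPM in NonIR 1, 2 and 3 behind a NonIR mean of 8.53 ± 11.4 CPM (SD). It stood at −5.70 without NonIR 3 and −9.90 without IR_NTN 5, and its 2 reads in IR_NTN against 312 in NonIR give a ratio of 0.00356 (exact Poisson 95% interval 0.000429 to 0.0130).

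Genes of the p53 and DNA damage response were higher in IR_NTN than in NonIR, 18 of 23 members, at a median of 0.51 (camera adjusted p = 0.000402; adjusted p = 0.729 with an estimated correlation). The list mean was 0.13 ± 0.13 against −0.26 ± 0.13 (SD), an exact permutation p of 0.0179, the smallest possible here. Adjusted over the list alone, Gdf15 was higher (1.44), as was the death receptor Eda2r (0.82), and the antiproliferative gene Btg2 was lower (−0.64), each at an edgeR p adjusted over the list alone of 0.0444, against 0 over all genes. Cdkn1a, the cell cycle inhibitor p21, had 10.8 ± 2.38 CPM in NonIR, 18.65 ± 8.21 in IR_GFP and 25.35 ± 12.03 in IR_NTN (SD), with edgeR adjusted p of 0.516 for IR_NTN against NonIR. Cell cycle genes were higher, 18 of 22 members, at a median of 0.58 (camera adjusted p = 0.000266; adjusted p = 0.729 with an estimated correlation), with a camera adjusted p of 0.296 without NonIR 3. Its member Ube2c stood at 2.47 (3.85 without NonIR 2) and was the 1 member past the threshold adjusted over the list alone (edgeR, 0.0397). T and NK cell genes were lower, 20 of 23 members, at a median of −0.43 (camera adjusted p = 0.0208; adjusted p = 0.835 with an estimated correlation), with 0.359 without NonIR 2 and 0.329 without IR_NTN 3. Of 29 lists, 3 passed camera and 0 with an estimated correlation (1 unadjusted), by directional fry (1 unadjusted) or by exact permutation after adjustment (1 unadjusted). Camera called 7 lists without NonIR 1, and 6 without IR_NTN 1 or IR_NTN 5. The mixed fry test called 2 lists in IR_NTN against NonIR, the p53 list (fry adjusted p = 0.0154) and the unfolded protein response (fry adjusted p = 0.00174). The unfolded protein response did not pass camera there (adjusted p = 0.176), with 9 of 18 members lower and a median of −0.03.

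Transcripts of the vector genes were also measured. Nrtn, the neurturin gene, had 4.86 ± 2.40 CPM in NonIR (SD, n = 3), 6.21 ± 3.62 in IR_GFP and 7.73 ± 4.01 in IR_NTN (SD, n = 5 each), and groups were not separated (edgeR adjusted p = 0.991 for IR_NTN against IR_GFP). Libraries held 56 to 161 Nrtn reads in IR_NTN, 37 to 140 in IR_GFP and 34 to 87 in NonIR, and whether the vector cDNA was of mouse is not given in the sources used here. The deposited EGFP and AAV2 sequences had 0 reads in every library, which over the 72209054 reads of IR_GFP allows up to 0.0415 CPM. The choline acetyltransferase gene Chat was too low to test, with 4, 2 and 4 reads in NonIR, IR_GFP and IR_NTN. The receptor genes did not pass: Ret stood at 27.1, 28.1 and 29.9 CPM in NonIR, IR_GFP and IR_NTN, and Gfra2 at 0.668, 0.796 and 0.348 (log2 fold change −1.18 in IR_NTN against IR_GFP, edgeR adjusted p = 0.760). The neuropeptide gene Vip stood at 0.4925, 1.71 and 0.4305 CPM, with 4.86 CPM in IR_GFP 1. The water channel gene Aqp5 had 176 ± 21.95, 195 ± 54.8 and 191 ± 24.4 CPM, and the muscarinic receptor gene Chrm3 stood at 3.385, 3.03 and 2.57 CPM.

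Genes that differed between IR_GFP and NonIR, and the other way between IR_NTN and IR_GFP, were counted. By edgeR, 0 genes passed in both with opposite signs, as did 0 in simulated unchanged groups, while 228 of 232 genes with an unadjusted p under 0.05 in both had opposite signs, which the shared libraries favour. With so few genes called in either comparison, a count of 0 was likely from the start. The 10 with the largest smaller fold change were Atp2a1, Igkv4-63, Esp16, Cd209b, Esp15, Ighv10-3, Ighv3-4, Igkv4-55, Esp31 and Igkv3-4, none of them called. Atp2a1 belongs to the skeletal muscle list, whose mean was 4.34 in IR_GFP 2 and −0.64 to 0.14 in the other IR_GFP libraries. Log2 fold changes correlated at r = −0.461 across genes, which are not independent replicates. Simulated unchanged groups gave −0.423 on average, from −0.446 to −0.388, a range that can be too narrow because each gene was drawn on its own. With separate IR_GFP libraries as controls in the comparisons, the mean r over 20 splits was −0.0219, from −0.191 to 0.187. The covariance was −0.0766 against −0.0515 in the simulated groups (−0.0566 to −0.0469). Over the 20 splits it averaged −0.00289, from −0.0372 to 0.0492. Both the correlation and the covariance thus lay beyond the simulated range, which can be too narrow. With separate controls both spread to either side of 0, so neither shows a reversal beyond what the shared libraries bring.

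Across libraries, the 20 most abundant genes took between 34.2% of reads (IR_GFP 1) and 60.2% (IR_GFP 3), and the TMM factor was 1.42 in IR_GFP 1 and 0.768 in IR_GFP 3. With library size as the only scaling, the median log2 fold change of all genes in IR_GFP against NonIR was 0.125 and 0 genes were called by edgeR, with 754 at an unadjusted p under 0.05. Correlations of log2 CPM between libraries of the same group were 0.927 to 0.977, and between groups 0.926 to 0.979.

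The remaining lists did not pass camera in any comparison. In IR_GFP against NonIR, medians were 0.15 for acinar secretory genes (camera adjusted p = 0.791), 0.12 for fluid and ion transport (0.475), 0.17 for basal and progenitor (0.5345), −0.16 for myoepithelial (0.299), 0.41 for Schwann and glia (0.1005), 0.05 for the GDNF family (0.350), 0.56 for MHC class I (0.350) and 0.17 for endothelial genes (0.475). They were 0.25 for adipocyte (0.5345), 2.93 for skeletal muscle (0.202), 0.06 for neighbouring gland (0.475), 0.02 for erythrocyte (0.5345), 0.01 for oxidative stress (0.847), −0.09 for mitochondrial respiration (0.0650) and −0.06 for immediate early genes (0.847). In the comparisons with IR_NTN, MHC class I genes had a median of −0.57 against IR_GFP (camera adjusted p = 0.0625). Single secretory genes stood out: in IR_GFP against NonIR, Smgc (−1.60), Cst10 (−3.83) and Smr3a (−4.345) were lower when adjusted over the acinar list alone, against 0 over all genes, and Smr3a and Cst10 were highest in NonIR 3, at 29.5 and 21.6 CPM. Amy1, an amylase of the neighbouring gland list, had 273 CPM in NonIR 3 and 32.2 and 68.6 in the other NonIR libraries. IR_GFP 2 stood apart in skeletal muscle genes at a list mean of 4.34, and the 3 members tested were lower in IR_NTN than in IR_GFP when adjusted over the list alone, against 0 over all genes. The highest MHC class I list mean was 1.42, in IR_GFP 4, with 0.64 in IR_GFP 2. Median, mean and direction of the test differed in sign in 20 of 87 list tests, 0 of them called: the acinar list in all 3 comparisons, the GDNF family, T and NK cell, neighbouring gland, erythrocyte, oxidative stress and immediate early lists in IR_GFP against NonIR, the fluid transport, duct, Schwann, GDNF family and adipocyte lists in IR_NTN against IR_GFP, and the basal, myoepithelial, endothelial, adipocyte, erythrocyte and mitochondrial lists in IR_NTN against NonIR. In the sex check list only Xist was tested, and it did not pass the threshold in any comparison.

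**Figure D3:**
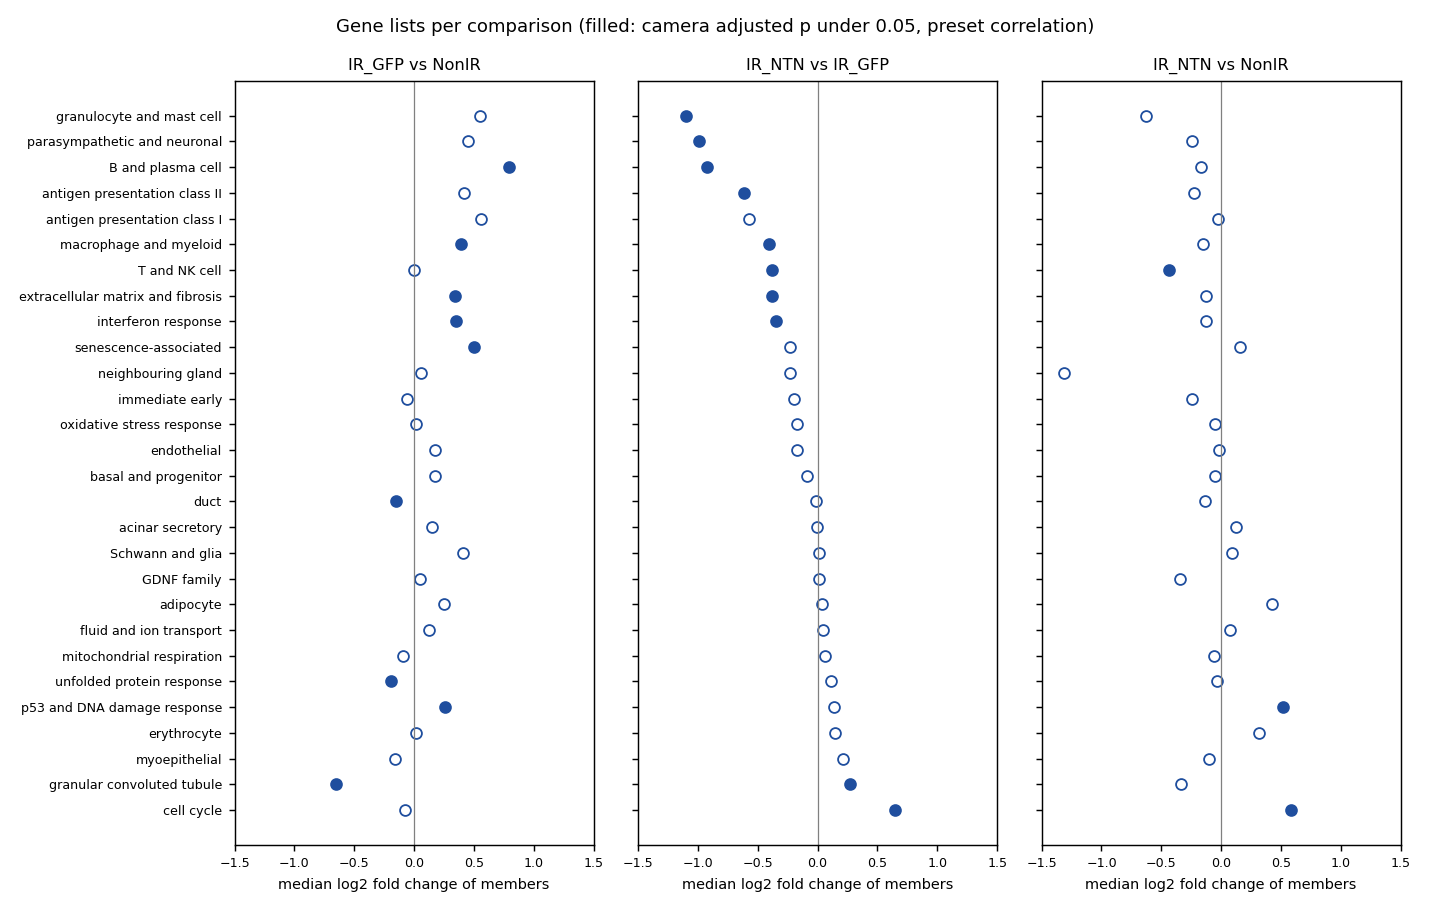
Median log2 fold change of 28 gene lists in the 3 comparisons; filled points passed camera at the preset correlation (adjusted p under 0.05), open points did not. Skeletal muscle, with 3 members tested, is left out of the plot, with medians of 2.93, −2.80 and 0.12, and the macrophage list lies at 0.39, −0.40 and −0.15.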

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

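Leaving out IR_GFP 1 and 2 together, as done in the other parts, was chosen after the results were seen; leaving out each library in turn was fixed earlier. Each measure of 1 group was searched for a library far from the other libraries of that group, by Dixon's ratio of gap to range; 98 groups of values were searched and 6 stood out, where chance gives about 1 in 20, or 4.9.

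IR_GFP 1 stood out in nerve genes. Its Vip CPM was 4.859, while the other IR_GFP libraries lay from 0.119 to 1.21, and its Schwann and glia list mean was 0.2274 against −0.04 to 0.02. This library is also the shallowest, with 9724304 reads, and has the lowest granular convoluted tubule list mean, −2.19. IR_GFP 2 stood out in skeletal muscle genes, with a list mean of 4.34 against −0.64 to 0.14 in the others. No biological explanation was tested for either library, since both belong to the same labelled group as their neighbours.

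IR_NTN 3 had 11434808 reads while the other IR_NTN libraries held 14438515 to 15378199, and its T and NK cell list mean was −0.9157 against −0.105 to 0.10. IR_NTN 5 had a cell cycle list mean of 0.7539 against 0.19 to 0.34. No biological explanation was tested for these.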

How the results depend on the processing

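Leaving out IR_GFP 1 and 2 together, the acinar secretory covariate and the exact permutation of list means were chosen after the results were seen. Values below are for IR_GFP against NonIR, IR_NTN against IR_GFP and IR_NTN against NonIR in that order, and the cause of each difference was not tested.

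By edgeR the counts of genes were 5, 3 and 3. DESeq2 size factors gave 5, 3 and 3, and the edgeR legacy form 5, 3 and 2. Library size alone gave 0, 0 and 0 (754, 573 and 479 at an unadjusted p under 0.05). Without a low-count filter they were 20, 10 and 4. The DESeq2 test gave 73, 38 and 31, which held 5, 3 and 2 of the genes called by edgeR. Limma-voom gave 0 (1126 unadjusted), 3 and 1. Fits of only the libraries compared gave 0 (1007), 0 (815) and 2. The threshold of 0.1 gave 13, 5 and 4, the acinar covariate 11, 8 and 7, and leaving out IR_GFP 1 and 2 together 1, 1 and 5. Leaving out 1 library at a time gave 0 to 17, 0 to 11 and 0 to 4 genes. No called gene turned direction in any alternative. Serping1 kept its call in 18 of 27 alternatives (log2 fold change −1.28 to −1.03), Dpt in 17 (−1.47 to −1.16), and in IR_GFP against NonIR Rab27a in 11 (−1.10 to −0.83) and Il1rn in 9 (−1.83 to −1.37).

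By camera the counts of lists were 9, 10 and 3, while other splits of the same libraries gave medians of 8, 8 and 4. With an estimated correlation they were 0, 1 and 0, by directional fry 0, 2 and 0, by mixed fry 1, 2 and 2, and by exact permutation 0, 0 and 0 after adjustment, with 1, 4 and 1 at an unadjusted p under 0.05. A lone list at the smallest possible p adjusts to 0.518, 0.230 and 0.518, so these counts of 0 say little about how firm the lists are. Without IR_GFP 1 and 2 together they were 3, 11 and 4. Leaving out 1 library at a time gave 4 to 12, 7 to 15 and 2 to 7. Lower macrophage and B and plasma cell lists, and the higher cell cycle list, in IR_NTN against IR_GFP passed camera in all 13 fits without 1 library. The interferon response list in IR_GFP against NonIR was the only list called by camera that turned direction: its camera adjusted p ran from 2.46e-05 without NonIR 2 to 0.955 without NonIR 3, where it was lower.

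The correlation of fold changes across genes in the comparisons sharing IR_GFP was −0.461; it ran from −0.548 without IR_GFP 4 to −0.392 without NonIR 3, and averaged −0.0219 when separate IR_GFP libraries served as controls, a construction that removes the sharing. Opposite-direction genes numbered 0 in each setting where they were counted. These were the main fit, DESeq2 size factors, CPM above 1 in at least 3 libraries and the replicate block. Each library left out in turn and the split IR_GFP libraries were counted too. Few genes were called there, so a count of 0 was likely from the start. The DESeq2 test and the fit without a low-count filter, which called more genes, were not counted in this way.

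The labels do not tie replicate numbers across groups. Over 11 pairs of libraries with the same number, residuals correlated from −0.43 to 0.28, with a median of −0.16. The median over 44 other pairs was 0.01. These residuals gave no sign of pairing by number but cannot exclude it. Other differences between libraries enter them too, as unlike numbers reached 0.53 (IR_GFP 5 with IR_NTN 2). With the replicate number as a block, gene counts were 0, 0 and 0 (1084, 691 and 879 unadjusted), list counts were 12, 16 and 5, and the correlation was −0.453.

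Depth limits the genes of very low level: Chat had 2 to 4 reads per group. Among genes with a mean of at least 20 reads, the test on simulated data found 44.7% to 67.7% of 2-fold changes. A 2-fold change of a single gene can therefore be missed here also at higher counts.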

Other observations

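The lists of fibroblast, complement, immunoglobulin and clock genes below, all tests of them, all tests of explanations, the count of other splits for IR_GFP against NonIR, and the counts of splits by unadjusted p were chosen only after the results were seen; the other counts of splits were fixed earlier.

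Fibroblast and complement genes were lower in IR_NTN than in IR_GFP. By edgeR 1 of 20 fibroblast and 1 of 12 complement genes were called, and 12 and 9 had an unadjusted p under 0.05. Of 20 fibroblast genes, chosen after Dpt and Pdgfra had been seen, 18 were lower, at a median log2 fold change of −0.72, and the list mean separated the groups completely (exact permutation p = 0.00794, the smallest possible). Against NonIR, 16 of the 20 were lower in IR_NTN, at a median of −0.46 (exact permutation p = 0.0179), and 15 were higher in IR_GFP, at a median of 0.20 (exact permutation p = 0.429). Of 12 complement genes, 12 were lower in IR_NTN than in IR_GFP, at a median of −0.72 (exact permutation p = 0.00794), and 11 were higher in IR_GFP than in NonIR, at a median of 0.43 (exact permutation p = 0.0357); 9 were lower in IR_NTN than in NonIR, at a median of −0.32 (exact permutation p = 0.0357). Among 92 immunoglobulin genes, which are near-identical copies and so uncertain singly, 88 were lower in IR_NTN than in IR_GFP, at a median of −2.12, with 0 called by edgeR and 62 at an unadjusted p under 0.05 (exact permutation p = 0.0317). Medians of these were 1.03 in IR_GFP against NonIR (exact permutation p = 0.357) and −1.15 in IR_NTN against NonIR (exact permutation p = 0.268). Since these lists were drawn from the same values, their p-values are not independent evidence.

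A candidate explanation of the lower immune and matrix genes in IR_NTN is that IR_NTN glands hold fewer macrophages, plasma cells and fibroblasts, or less active ones. Another is a larger share of secretory epithelium, which would lower the markers of every other cell type alike. Relative to endothelial genes, the B and plasma cell list mean was lower by more than its spread (difference −0.999, exact permutation p = 0.0238), which argues against epithelial share as the whole cause for B and plasma cells. For macrophages the same comparison gave a difference of −0.35 (exact permutation p = 0.0714). The acinar secretory list mean differed between the groups by −0.02 (exact permutation p = 0.960). With the acinar and granular convoluted tubule list means as covariates, the macrophage list mean stayed lower in IR_NTN (difference −0.43, SE 0.11, exact permutation p = 0.00794; −0.42 without covariates). This argues against the share of these secretory cells, as those lists measure it, as the whole cause for macrophages. Each gene counts alike in those lists, whatever its level. The share of reads in the 20 most abundant genes was 51.2 ± 5.19% in IR_NTN and 47.7 ± 10.0% in IR_GFP (SD). That share was not used as a covariate, so a secretory share measured in this way stays open for macrophages. For matrix genes, camera still passed with the acinar covariate alone (adjusted p = 1.82e-06; 6.60e-10 to 0.555 over all alternatives, the highest with an estimated correlation). Their list mean did not separate the groups without covariates (−0.36, exact permutation p = 0.0873), and it differed by −0.18 with both (SE 0.19, exact permutation p = 0.357). The comparison with endothelial genes gave −0.29 (exact permutation p = 0.1825), so for matrix genes the epithelial share cannot be told apart from fewer or less active fibroblasts with 5 libraries per group. Lymphoid tissue taken along with some IR_GFP glands would bring T cells with the B cells; the difference between those lists was −0.73 (exact permutation p = 0.103), so it stays open.

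The libraries that stood apart, IR_GFP 1 and 2, are not the whole source of the macrophage difference: without them the list mean was still lower in IR_NTN by 0.37 (difference −0.37, exact permutation p = 0.0357). A count of cells by staining for macrophage, plasma cell and fibroblast markers in separate glands would bear on this, and was not analysed here. By itself it may not tell fewer cells from a larger epithelial share or from less active cells.

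Clock genes may differ between NonIR and the other groups. Tef alone passed the threshold; in IR_GFP against NonIR, Dbp stood at 1.62 and Per3 at 1.17, and Arntl, whose transcript peaks at the opposite time, at −0.87. Output genes minus antiphase genes differed by 1.05 (exact permutation p = 0.0357) in IR_GFP against NonIR, 0.61 (exact permutation p = 0.0179, the smallest possible) in IR_NTN against NonIR and −0.43 (exact permutation p = 0.103) in IR_NTN against IR_GFP. These genes were picked because Tef was called, so the test in part restates what prompted it; without Tef the differences were 0.99, 0.59 and −0.41 (exact permutation p = 0.0357, 0.0179 and 0.127). Taken alone, output genes differed by 0.64, 0.51 and −0.13 in these 3 comparisons (exact permutation p = 0.0357, 0.0179 and 0.421). Antiphase genes alone differed by −0.41, −0.11 and 0.30 (exact permutation p = 0.0357, 0.143 and 0.0159), so for them IR_NTN lay nearer to NonIR than to IR_GFP. The mean of 8 further clock- or temperature-driven genes, among them Cirbp and Rbm3, differed by 0.13 in IR_GFP against NonIR (exact permutation p = 0.161), −0.21 in IR_NTN against IR_GFP (exact permutation p = 0.0397) and −0.08 in IR_NTN against NonIR (exact permutation p = 0.411). A different hour of harvest could give such differences, and the hour is not given in the sources used here, so hour, irradiation and vector cannot be told apart for these genes.

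Other splits of the same libraries were tested with edgeR and camera. For IR_GFP against NonIR, 4 of the 56 splits called as many genes as the real one (5, highest other 16) and 17 as many lists (9, highest other 13), so chance is not excluded for either count. By genes at an unadjusted p under 0.05, 12 of the 56 had as many (1293, highest other 2586). For IR_NTN against IR_GFP, 100 of the 126 distinct splits were drawn, and 3 of them called as many genes (3, highest other 694), while 31 of 100 had as many genes at an unadjusted p under 0.05 (896, highest other 2942), so chance is not firmly excluded for a count this small. The other 2 called 596 and 694 genes, and the real count was itself 0 without IR_GFP 1, IR_NTN 1, IR_NTN 4 or IR_NTN 5 (678 to 939 at an unadjusted p under 0.05) and in a fit of only these groups (815 unadjusted), where DESeq2 called 38. The split that called 694 genes set IR_GFP 1, 2 and 5 with IR_NTN 2 and 3 against the rest. It followed the share of reads in the 20 most abundant genes. That share was 34.2% (IR_GFP 1) to 49.8% (IR_GFP 2) on this side and 52.6% to 60.2% on the other. TMM factors were 0.986 to 1.42 on this side and 0.768 to 0.946 on the other. This points to a structure of the samples beyond their labelled groups, whose source was not tested. As many lists came from 23 of 100 splits (10, highest other 16), so chance is not excluded for the list count. For IR_NTN against NonIR, 1 of 56 splits, the real one, called as many genes (3, highest other 0), while 8 of 56 had as many at an unadjusted p under 0.05 (1174, highest other 1492). The count of called genes was 0 without NonIR 2, NonIR 3, IR_NTN 3 or IR_NTN 5 (894 to 1245 unadjusted), so here too chance is not firmly excluded. In this comparison 38 of 56 called as many lists (3, highest other 12), so chance is not excluded for the list count. The median number of lists in the other splits was 8 for IR_GFP against NonIR, 8 for IR_NTN against IR_GFP and 4 for IR_NTN against NonIR.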
